A study of Homo sapiens with 10 samples.

How the data were processed

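RNA of 5 human B-lineage cell lines was sequenced after treatment with CMLD010509, a compound the study used to inhibit translation, at 50 nM for 6 hours, or with the vehicle DMSO. The 4 lines NCI-H929, MM1S, OPM2 and U266 are multiple myeloma lines, and NAMALWA is a Burkitt lymphoma line. Total RNA was extracted with a column kit and libraries were made with an NEBNext RNA kit, per the labels' protocols. Each line gave 1 library per group, and the cell line serves as the replicate. The lines are numbered 1 (NCI-H929), 2 (NAMALWA), 3 (MM1S), 4 (OPM2) and 5 (U266).

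The deposited table holds RPKM values (reads scaled to gene length and to a read total of the library) of 52576 genes in 10 columns. Reads were aligned with TopHat2 to GRCh37 and handled with Picard, per the submitters' processing notes, which give no versions. The counting tool, the annotation release, the strand setting and any filter are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies or pseudogenes may have shared reads. Gene identifiers and symbols are those of the table. The reference annotation at hand (GENCODE release 29) is on a later build, so that no coordinates are printed, and it served only for the lengths of single-exon genes, used to recover read totals, and for GC content, which was available for 95.6% of the genes tested.

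Of the 10 columns, 8 carry the names of the 4 myeloma lines and were used. The other 2 columns carry a name that none of the sample labels has, and they were not used in any step. The NAMALWA libraries were therefore not analysed here. The planned comparisons over all 5 lines, between NAMALWA and the myeloma lines, and of basal levels in NAMALWA were not run. The gene lists, planned on the 5-line fit, were tested on the 4-line fit.

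The depth was recovered from the steps of the RPKM values, since 1 read in a gene of known length is worth a fixed RPKM. Totals came to 46214935 reads (DMSO) and 46774444 reads (CMLD010509) in NCI-H929, 47620365 and 50417762 reads in MM1S, 48770145 and 43285225 reads in OPM2, and 24865004 and 51042370 reads in U266. The length of each gene was then inferred as the smallest whole length that gave whole reads in every library, within about 0.02 reads. The gene reads so recovered made up 99.8 to 99.9% of the totals. The totals may therefore count reads in genes rather than all mapped reads. Such a length was found for 100.0% of the 14086 genes tested, which is no independent check, since whole reads were the criterion of the search. The inferred length equalled the reference length in 70.1% of 1490 single-exon genes checked. Inferred lengths, or reads from them, entered voom, thinning, the length trend and the matching on length. In a gene of 1 kb, 1 read was worth 0.0196 to 0.0231 RPKM in 7 libraries and 0.0402 RPKM in the U266 DMSO library, so that low values are coarsest in that library. This resolution covers counting error only.

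The main comparison used limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with the cell line as a block and the empirical Bayes trend, over genes with a mean RPKM of at least 1 in the 8 libraries. The test was two-sided, with Benjamini-Hochberg adjustment over all 14086 genes and a threshold of 0.05. The residual degrees of freedom were 3 and the prior added 5.6. Each SE of a log2 fold change is limma's moderated SE, which draws the spread of a gene towards that of other genes. For genes that vary most between lines it is smaller than the 4 lines alone would give. FOSL2, with an SE of 0.37, had an SD of 1.19 between the lines. Fold changes are on the log2(RPKM + 1) scale, which understates the change of low genes. The p-values rest on the spread of the differences between lines, moderated by the prior. This spread holds differing responses of the lines and the noise of single libraries, which cannot be told apart. The block was part of the planned model: the 2 libraries of a number come from the same cell line. Their deviations from the group means correlated at 0.92 to 0.94 across genes, and those of different lines at -0.41 to -0.22. Within a line there is 1 library per group, so that differences in a line are given as values with no test.

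There were 28 gene lists, 25 of which had at least the 5 measured members a test required. Lists were tested with limma's camera, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. As planned, limma's fry, which tests a list without setting it against other genes, was run beside camera. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named the 10 largest increases and the 10 largest decreases among genes past the threshold that moved the same way in every line, the 3 largest increases and decreases in each line among genes with an RPKM of at least 5 in 1 of its libraries, and members of the lists. Symbols of small RNA classes (among them small nucleolar, small nuclear and micro RNAs), XIST and Y-linked genes were left out of this rule. The symbol patterns did not cover the short features RMRP and AC112777.1, which the rule named. A few list members are not reported here.

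On simulated values for 14086 genes with 200 genes changed, the 4-line comparison recovered 25.8% of the genes with a log2 change of 0.585, 67.2% of those with a change of 1 and 92.5% of those with a change of 2, with 2 false calls. The data differ from this setting, since 36.1% of the genes tested passed there, and the simulation shuffled the residual spreads between genes. These shares therefore need not hold for the real comparison. In the same simulation camera called a list shifted by -0.5 and none (0) of the 24 other lists. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera with the preset correlation calls lists of correlated genes.

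The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean RPKM of at least 5, upper-quartile scaling, quantile normalization, centring on the median, no block, robust empirical Bayes, and leaving out each line in turn. A count test planned for the case that counts were deposited was not run, since the table holds RPKM. Chosen after seeing the data were limma voom on the recovered reads (5561 genes called), library totals without mitochondrial, ribosomal protein and immunoglobulin genes, removal of each library's GC content and length trend with the same block, the gene lists over only the genes with GC content, and thinning of every library to the reads of the shallowest. Figures were drawn with matplotlib.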

Results

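The data are RPKM values from RNA sequencing of 4 human multiple myeloma cell lines, NCI-H929, MM1S, OPM2 and U266, each treated with 50 nM CMLD010509 for 6 hours or with DMSO. Each group held 4 libraries, 1 per line. Totals were 24865004 to 48770145 reads in the DMSO libraries and 43285225 to 51042370 reads in the CMLD010509 libraries, and the U266 DMSO library was the shallowest. The plasma cell identity of the lines was visible in every library. The median RPKM of the plasma cell markers was 24.6 to 82.7 across the 8 libraries, against at most 0.373 for the B cell and germinal centre markers and at most 0.196 for the markers of T and NK cells, myeloid cells, and fibroblasts and epithelium. Some B cell markers were expressed all the same. In DMSO, 11 of 24 reached an RPKM of 1 in MM1S, 9 in U266, 7 in OPM2 and 4 in NCI-H929. CD74 stood at 588 and HLA-DRA at 241 RPKM in the MM1S DMSO library.

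The first comparison asked which transcripts change when myeloma cells are treated with CMLD010509, which the study used as an inhibitor of translation. Of 14086 genes tested, 5081 passed the threshold (limma with cell line as block, Benjamini-Hochberg adjusted), 3233 higher and 1848 lower with CMLD010509. Among these, 3103 of the higher and 1752 of the lower genes moved the same way in all 4 lines, and 502 rose and 99 fell at least 2-fold. The largest increase was that of JUN, a subunit of the AP-1 transcription factor, with a log2 fold change of 3.72 ± 0.19 (moderated SE, 4 lines) and an adjusted p of 0.000114. JUN stood at 17.2 ± 9.30 RPKM in DMSO and 289 ± 272 RPKM with CMLD010509 (SD, n = 4). TSC22D3, a glucocorticoid-induced regulator also known as GILZ, rose by 2.39 ± 0.11 (adjusted p = 0.000114), from 7.94 ± 2.80 to 44.7 ± 8.01 RPKM. TXNIP, an inhibitor of thioredoxin and of glucose uptake, rose by 2.32 ± 0.24, and RHOB, a small GTPase, by 2.31 ± 0.17. The AP-1 member FOSL2 rose by 2.27 ± 0.37, the MAP kinase phosphatase DUSP10 by 2.17 ± 0.16 and the immediate early gene IER2 by 2.15 ± 0.31. ZNF184, a zinc finger gene, rose by 2.14 ± 0.12, the transcription factor KLF6 by 2.09 ± 0.13 and RGS1, a regulator of G protein signalling, by 1.92 ± 0.19.

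The largest decrease was that of HSPA8, the constitutive cytosolic HSP70 chaperone, with a log2 fold change of -2.96 ± 0.25 (SE, 4 lines) and an adjusted p of 0.000335, from 731 ± 207 to 112 ± 85.6 RPKM (SD, n = 4). Its pseudogene HSPA8P1 stood at -2.26 ± 0.20 and is uncertain, since it may share reads with HSPA8. The other genes of the 10 largest decreases were BRI3BP at -1.93 ± 0.15, the segregase VCP at -1.72 ± 0.22, the poly(ADP-ribose) polymerase PARP1 at -1.69 ± 0.12, the fatty acid synthase FASN at -1.65 ± 0.17, the single-strand DNA binding protein RPA1 at -1.55 ± 0.14, the heterochromatin protein CBX5 at -1.54 ± 0.13, RP11-887P2.3 at -1.53 ± 0.12 and the chaperone HSP90AA1 at -1.50 ± 0.17. The 20 genes of both sets carried adjusted p-values between 0.000114 and 0.00278.

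**Figure D1:**
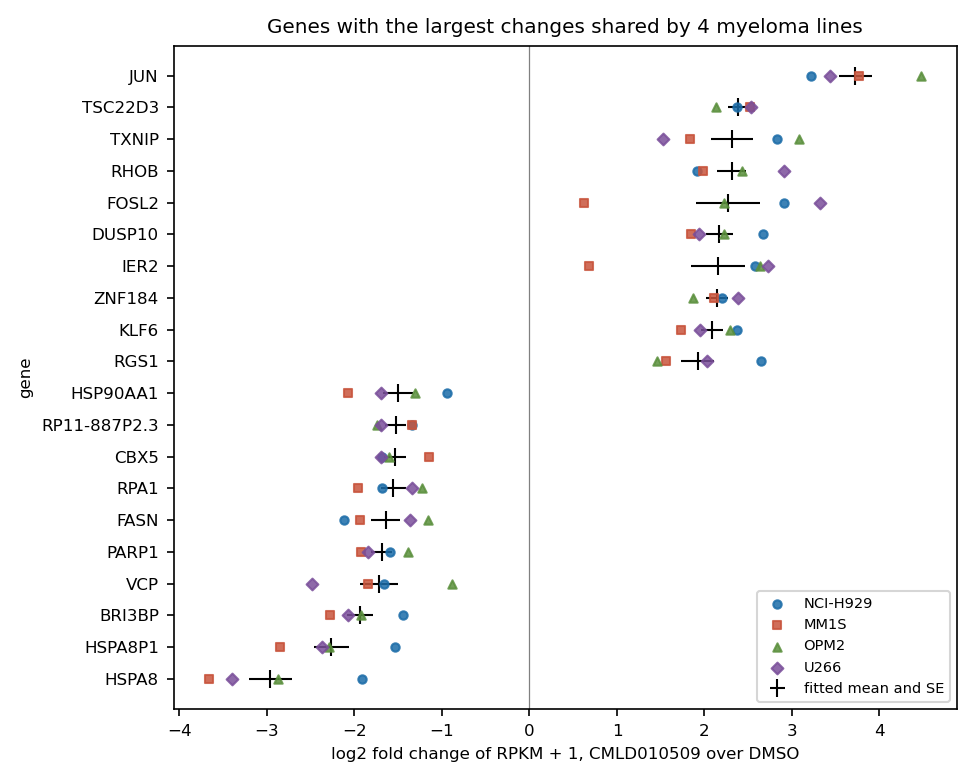
Log2 fold change of RPKM + 1 (CMLD010509 over DMSO, horizontal axis) of the 10 largest increases and 10 largest decreases shared by 4 myeloma lines. Coloured points are the single lines and black bars are the fitted mean with its moderated SE. JUN lies highest at 3.72 and HSPA8 lowest at -2.96, and for FOSL2 and IER2 the MM1S point lies apart at 0.62 and 0.68.

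The balance of higher and lower genes depended on the scaling. With the authors' RPKM scaling 63.6% of the called genes were higher, against 50.3% with upper-quartile scaling, 47.9% with quantile normalization and 34.8% after centring each library on its median. The median log2 fold change of all genes was 0.085, and it shifted by -0.113 under quantile normalization and by -0.194 under centring. Centring thus took it past 0, to -0.109. The sum of all RPKM values was 375853 to 396189 in the CMLD010509 libraries, against 423556 to 455673 in the DMSO libraries. Scaling to equal sums, which would raise the CMLD010509 values against DMSO, was not run. Without NCI-H929 3149 genes passed, and without OPM2 3382 genes passed. With the cell line left out of the model limma called 0 genes, with 1319 genes at an unadjusted p under 0.05. Without a filter on low values the number of genes called was 1943.

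Of 36 measured immediate early genes, 29 rose and 1, DUSP2, fell, with a median log2 fold change of 1.09. Camera gave this list an adjusted p of 4.3e-10, and the adjusted p was 0.25 with an estimated correlation. Among the members JUND rose by 1.75 ± 0.19, ATF3 by 1.61 ± 0.17, BTG1 by 1.52 ± 0.09 and FOS by 0.92 ± 0.21 (SE, 4 lines). The DUSP2 call was lost with both smaller pseudocounts and without each of NCI-H929, MM1S and OPM2 (adjusted p up to 0.166). With p-values adjusted over the list alone, 31 rose and 1 fell. Of 23 measured NF-kB targets, 13 rose and 0 fell, and adjusted over the list alone the counts were the same. Camera gave an adjusted p of 3.96e-05, and the adjusted p was 0.25 with an estimated correlation. The deubiquitinase and NF-kB inhibitor TNFAIP3 rose by 1.83 ± 0.20, NFKBIE by 1.31 ± 0.15, NFKB2 by 1.31 ± 0.22 and RELB by 1.28 ± 0.24. Of 31 interferon-stimulated genes, 16 rose and 1, BST2, fell (camera adjusted p = 0.000594, and adjusted p = 0.462 with an estimated correlation). SAMD9L rose by 1.29 ± 0.12 and IFIT3 by 1.05 ± 0.28, while BST2 stood at -0.79 ± 0.13. IFIT3 missed the threshold without OPM2 (adjusted p = 0.0527), and its log2 fold change ranged from 0.65 to 1.31 without 1 line. When adjusted over the list alone, 19 rose and 1 fell.

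Of 33 measured members of the integrated stress response, the program downstream of ATF4, 15 rose, 1 fell and 17 did not pass (camera adjusted p = 0.00762, and adjusted p = 0.462 with an estimated correlation). ATF4 itself rose by 1.10 ± 0.11, DDIT3 by 1.44 ± 0.10, PPP1R15A by 1.21 ± 0.15 and TRIB3 by 0.92 ± 0.16, and the glutamyl-prolyl-tRNA synthetase EPRS stood at -0.47 ± 0.11. Adjusted over the list alone, 17 rose and 1 fell. With centring 10 rose and 3 fell, with a median of 0.24 against 0.43. The median of this list was 0.05 in NCI-H929 against 0.32 to 0.57 in the other lines. Without U266 the camera adjusted p was 0.0585. Of 29 members of the unfolded protein response of the endoplasmic reticulum, 3 rose and 4 fell, and 2 rose and 4 fell adjusted over the list alone. The counts were 4 and 2 under quantile normalization and 2 and 10 with centring on the median. The lines went different ways, with list medians of 0.30 in OPM2, 0.08 in MM1S, -0.21 in NCI-H929 and -0.52 in U266. The DnaJ chaperone DNAJB9 rose by 1.32 ± 0.15 and the COPII coat protein SEC24D by 1.38 ± 0.24, while DERL1, a retrotranslocation factor, stood at -0.93 ± 0.13 and the protein disulfide isomerase TXNDC5 at -1.06 ± 0.15. The camera adjusted p of this list was 0.0951, and the adjusted p was 0.758 with an estimated correlation. Its adjusted p was 0.0332 without MM1S and 0.0035 without OPM2.

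Of 78 measured cytosolic ribosomal protein genes, 76 fell, 0 rose and 2, among them RPLP1, did not pass, with a median log2 fold change of -0.52. The camera adjusted p was 4.01e-28, and the adjusted p was 0.388 with an estimated correlation. Under quantile normalization 29 of the 78 fell and the median was -0.22. RPL27A fell by 0.78 ± 0.12 on the log2 scale, from 115 ± 11.7 to 67.1 ± 12.9 RPKM (SD, n = 4). Adjusted over the list alone, 78 fell. The share of gene reads on these genes went from 5.0 to 2.97% in NCI-H929, 4.52 to 3.44% in MM1S, 5.45 to 3.93% in OPM2 and 5.09 to 3.68% in U266. Of 42 translation initiation factors, 15 fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 3.1e-05, and adjusted p = 0.388 with an estimated correlation). The RNA helicase DDX3X stood at -1.23 ± 0.16, EIF4B, a cofactor of the eIF4A helicase, at -0.92 ± 0.12, the poly(A)-binding protein PABPC1 at -0.62 ± 0.14 and EIF4A1 at -0.39 ± 0.10. With upper-quartile scaling 20 of these factors fell and 0 rose, and with centring on the median 23 fell and 0 rose. Under quantile normalization the calls of PABPC1 and EIF4A1 were lost, with log2 fold changes of -0.25 (adjusted p = 0.171) and -0.13 (adjusted p = 0.33). EIF1 rose by 0.49 ± 0.14 and EIF5 by 0.36 ± 0.10, both calls being lost with upper-quartile scaling and with centring, and that of EIF5 also after removal of the GC content and length trend (0.19, adjusted p = 0.128). With NCI-H929 left out the calls of EIF1, EIF5 and EIF4A1 were lost too, with MM1S left out those of EIF1 and EIF4A1, and with OPM2 left out those of EIF1 and EIF5 (adjusted p up to 0.118, 0.0679 and 0.0582 for EIF1, EIF5 and EIF4A1).

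**Figure D2:**
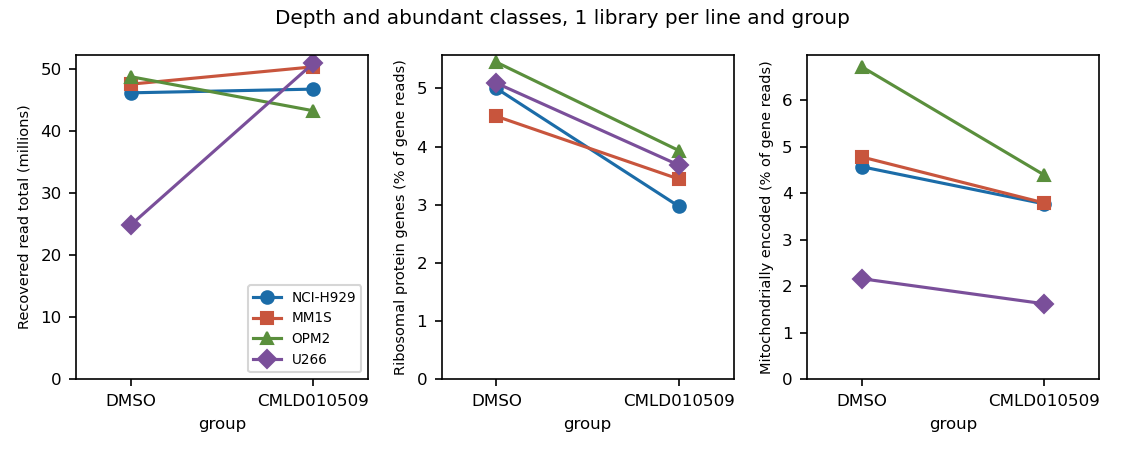
Recovered read totals, share of gene reads on ribosomal protein genes and share on mitochondrially encoded genes in percent (vertical axes), with 1 point per library and a line joining the DMSO and CMLD010509 libraries of each cell line. The ribosomal protein and mitochondrial shares were lower with CMLD010509 in all 4 lines, and the U266 DMSO library had the fewest reads, 24865004.

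Of 8 measured mitochondrially encoded genes, which were included as a sign of RNA quality, 8 fell, with a median of -0.46 that became -0.05 with 0 genes called under quantile normalization. The camera adjusted p was 0.000102, and the adjusted p was 0.388 with an estimated correlation and 0.583 under quantile normalization. MT-CYB stood at -0.56 ± 0.11, and adjusted over the list alone 8 fell. Of 35 nuclear genes of oxidative phosphorylation, 20 fell and 0 rose, among them SDHC at -0.54 ± 0.10 and UQCRH at -0.54 ± 0.09, and 26 fell adjusted over the list alone, while 13 fell under quantile normalization (camera adjusted p = 1.94e-09, and adjusted p = 0.388 with an estimated correlation). Of 22 glycolysis genes, 16 fell and 0 rose, with a median of -0.60 (camera adjusted p = 2.52e-08, and adjusted p = 0.35 with an estimated correlation). The phosphoglycerate mutase PGAM1 fell by 1.47 ± 0.13 on the log2 scale, PFKM by 1.03 ± 0.17, the glucose transporter SLC2A1 by 0.78 ± 0.14 and LDHA by 0.66 ± 0.10. When adjusted over the list alone, 18 fell and 1 rose. Of 7 genes of the MondoA/ChREBP list, which holds responsive genes and the regulators MLXIP and MLX, 4 rose. The genes that rose were TXNIP, ARRDC3 by 1.29 ± 0.12, KLF10 by 1.25 ± 0.14 and ARRDC4 by 1.09 ± 0.33. MLXIP and MLX stood at -0.05 ± 0.14 and -0.01 ± 0.13. Adjusted over the list alone 4 rose (camera adjusted p = 0.0278, and adjusted p = 0.388 with an estimated correlation). ARRDC4 missed the threshold without NCI-H929, at 0.64 ± 0.24, and without OPM2, at 1.02 ± 0.39 (adjusted p up to 0.0942). Over the genes with GC content only, which leave out TXNIP, the call of the list was lost (adjusted p = 0.0985), and on the same genes with the GC content and length trend removed the adjusted p was 0.0673, with ARRDC3 at 1.12 ± 0.10, KLF10 at 1.22 ± 0.14 and ARRDC4 at 1.01 ± 0.32.

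Of 21 heat shock genes measured, 13 fell, 1 rose and 7 did not pass, also when adjusted over the list alone, and the median log2 fold change was -0.94. In the single lines the list median was -0.24 in NCI-H929, -1.03 in MM1S, -0.61 in OPM2 and -0.74 in U266. The camera adjusted p was 2.57e-07, and the adjusted p was 0.388 with an estimated correlation. Beside HSPA8 and HSP90AA1, the HSP90 activator AHSA1 stood at -1.41 ± 0.11, the mitochondrial chaperonins HSPE1 and HSPD1 at -1.16 ± 0.12 and -1.05 ± 0.12, and HSP90AB1 at -0.96 ± 0.11. DNAJB4 rose by 0.48 ± 0.15, a call lost with upper-quartile scaling, quantile normalization and centring, and without each of NCI-H929, MM1S and OPM2 (adjusted p up to 0.155). Of 34 proteasome subunits, 13 fell, PSMB5 with -0.79 ± 0.13, and 1 rose, the immunoproteasome subunit PSMB9, with 0.32 ± 0.11, whose call was lost with upper-quartile scaling, quantile normalization and centring, and without each of NCI-H929, MM1S and OPM2 (adjusted p up to 0.152). When adjusted over the list alone, 14 fell and 1 rose (camera adjusted p = 4.61e-07, and adjusted p = 0.411 with an estimated correlation). The lower subunits numbered 21 with upper-quartile scaling, 24 with centring and 9 with quantile normalization. Of 24 cholesterol genes, 5 fell and 1, the mevalonate kinase MVK, rose by 0.85 ± 0.12, and the counts were the same adjusted over the list alone. INSIG1 stood at -0.90 ± 0.17 (camera adjusted p = 0.0191, and adjusted p = 0.462 with an estimated correlation), and without MM1S the camera adjusted p was 0.086. The cholesterol genes that fell numbered 8 with upper-quartile scaling and with quantile normalization and 9 with centring.

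**Figure D3:**
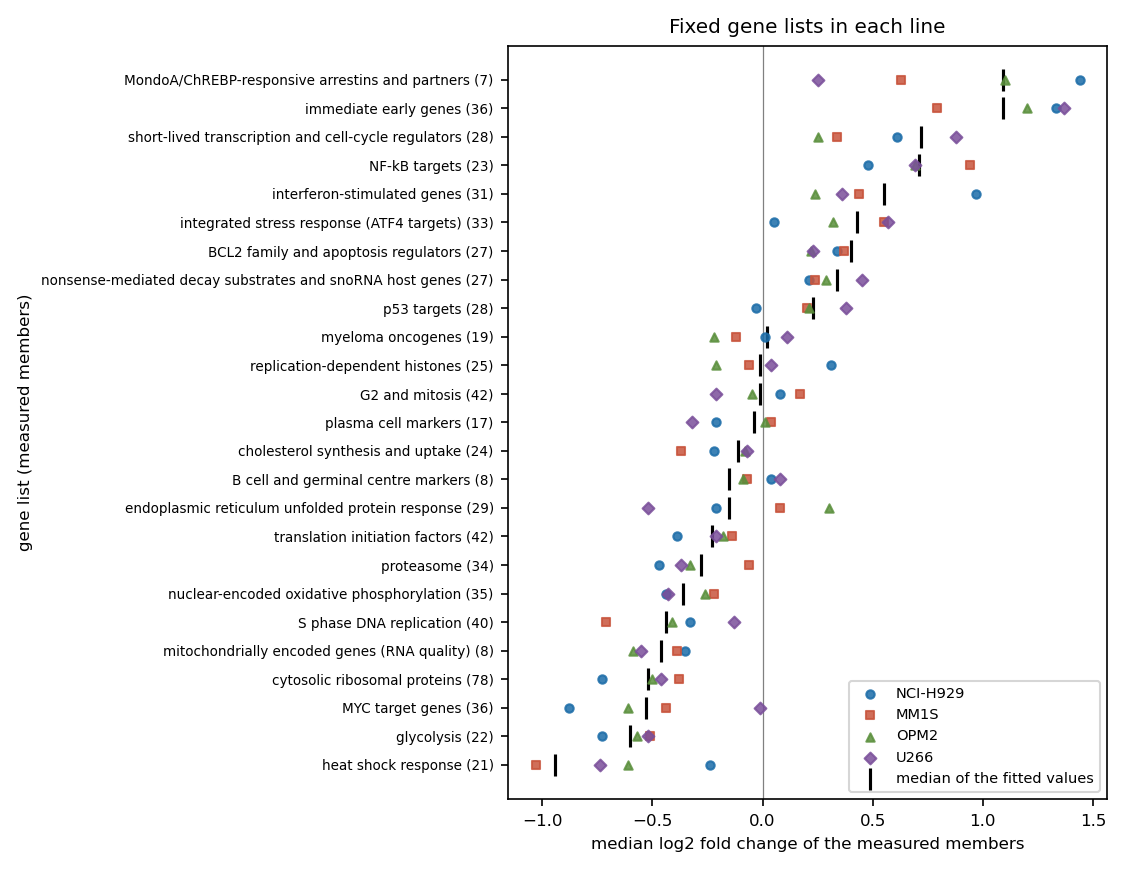
Median log2 fold change of the measured members (horizontal axis) of each fixed gene list with at least 5 measured members, with the number measured in brackets. Coloured points are the single lines and black bars the median of the fitted values; the bars run from -0.94 for the heat shock list to 1.09 for the immediate early and MondoA/ChREBP lists.

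The next question was what happened to transcripts of myeloma oncogenes and of their targets. Of 19 measured oncogenes, 4 rose and 4 fell, also when adjusted over the list alone. MYC rose by 0.97 ± 0.22 (adjusted p = 0.0102), MAF by 0.77 ± 0.16, the anti-apoptotic BCL2L1 by 0.51 ± 0.16 and MCL1 by 0.47 ± 0.13 (adjusted p = 0.0217). The calls of BCL2L1 and MCL1 were lost with upper-quartile scaling and with centring, and MCL1 missed the threshold without each of NCI-H929, MM1S and OPM2 (adjusted p up to 0.101), as BCL2L1 did without each of NCI-H929, OPM2 and U266 (up to 0.16). The integrin ITGB7 stood at -1.23 ± 0.12, the kinases PIM2 and CDK4 at -0.83 ± 0.19 and -0.64 ± 0.16, and IRF4 at -0.47 ± 0.14. The call of CDK4 was lost without NCI-H929 and without OPM2 (adjusted p up to 0.0711), and that of IRF4 without each of MM1S, OPM2 and U266 (up to 0.139) and with quantile normalization, as was that of PIM2. In 1 line each, BCL2L1 and IRF4 went against their call. BCL2L1 went from 116 to 111 RPKM in MM1S, and IRF4 from 139 to 143 RPKM in NCI-H929. CDK4 hardly moved in U266, from 59.1 to 57.3 RPKM. CCND1 had a log2 fold change of 0.026 ± 0.11 and MDM2 one of 0.21 ± 0.19, and neither passed. The median of the list was 0.02 and turned to -0.08 with upper-quartile scaling, where 2 rose and 6 fell, and to -0.17 with centring, where 2 rose and 7 fell, and its camera adjusted p was 0.282 (adjusted p = 0.646 with an estimated correlation). Of 36 MYC target genes, 19 fell and 0 rose, with a median of -0.53 (camera adjusted p = 4.15e-10, and adjusted p = 0.388 with an estimated correlation). The pyrimidine synthesis enzyme CAD fell from 30.2 ± 9.34 to 13.0 ± 5.60 RPKM (SD, n = 4), and the nucleolar proteins NPM1 and NCL stood at log2 fold changes of -0.72 ± 0.12 and -0.71 ± 0.15. Adjusted over the list alone, 23 fell. The median of this list was -0.01 in U266 and between -0.88 and -0.44 in the other lines.

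Among 27 regulators of apoptosis, 14 rose and 1 fell, also when adjusted over the list alone. For the list camera gave an adjusted p of 0.0154, and the adjusted p was 0.388 with an estimated correlation. Among the genes that rose were BIRC3 at 1.17 ± 0.20, BIRC2 at 1.17 ± 0.13, APAF1 at 0.89 ± 0.16, BAK1 at 0.88 ± 0.14, BBC3 at 0.82 ± 0.19 and PMAIP1 at 0.68 ± 0.14. BIRC5 stood at -0.50 ± 0.11. With centring 10 of the regulators rose and 3 fell, with a median of 0.21 against 0.40. BBC3 missed the threshold without MM1S (adjusted p = 0.0529). Of 28 p53 targets, 8 rose and 2 fell, also adjusted over the list alone, with GADD45A at 1.36 ± 0.32 and SESN2 at 1.09 ± 0.16, while CDKN1A, at 0.34 ± 0.19, did not pass. With centring on the median, 5 of these targets rose and 6 fell, with a median of 0.04 against 0.23 as reported. For this list camera gave an adjusted p of 0.269, and the adjusted p was 0.571 with an estimated correlation. Of 28 short-lived regulators, 13 rose and 0 fell, and 14 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.004, and adjusted p = 0.388 with an estimated correlation).

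Of 40 genes of DNA replication, 22 fell and 3 rose (camera adjusted p = 2.64e-07, and adjusted p = 0.411 with an estimated correlation). The uracil-DNA glycosylase UNG stood at -1.34 ± 0.25, the helicase subunit MCM3 at -0.91 ± 0.10 and the ribonucleotide reductase subunit RRM2 at -0.76 ± 0.11, while the licensing factor CDC6 rose by 0.71 ± 0.11. Adjusted over the list alone, 24 fell and 3 rose, and 28 fell and 1 rose with centring. Of 42 genes of G2 and mitosis, 7 rose and 5 fell, and 7 rose and 4 fell adjusted over the list alone. The balance turned with the scaling, to 6 higher and 8 lower genes with upper-quartile scaling and 3 higher and 12 lower with centring on the median. CDC20 rose by 0.59 ± 0.13 (lost with centring, adjusted p = 0.0624) and AURKA by 0.54 ± 0.11, and MAD2L1 stood at -0.63 ± 0.14 (camera adjusted p = 0.446, and adjusted p = 0.799 with an estimated correlation). Of 25 replication-dependent histone genes, 2 rose and 1, HIST1H2BK, fell (camera adjusted p = 0.448, and adjusted p = 0.799 with an estimated correlation), and adjusted over the list alone 0 rose and 1 fell. With centring 0 rose and 3 fell. Of 27 substrates of nonsense-mediated decay and snoRNA host genes, 11 rose and 2 fell, also adjusted over the list alone. UPF2, a decay factor, rose by 1.07 ± 0.13 and SNHG10 stood at -0.65 ± 0.13. With camera the adjusted p was 0.151, and the adjusted p was 0.388 with an estimated correlation. It was 0.0124 under quantile normalization and 0.03 without NCI-H929, while with centring 7 of the 27 rose and 5 fell, with a median of 0.14 against 0.34 as reported.

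Of 17 plasma cell markers, 2 rose and 6 fell, also when adjusted over the list alone, and 2 rose and 3 fell under quantile normalization. SDC1, which encodes CD138, stood at -0.97 ± 0.14, going from 289 ± 207 to 144 ± 87.1 RPKM (SD, n = 4), and the adaptor LAX1 rose by 1.77 ± 0.12 (camera adjusted p = 0.153, and adjusted p = 0.619 with an estimated correlation). Of 8 B cell and germinal centre markers, 2 rose, the repressor BACH2 by 1.45 ± 0.17 and CIITA by 0.66 ± 0.18 (lost with quantile normalization, with centring, without NCI-H929 and without OPM2, adjusted p up to 0.0938), also adjusted over the list alone, while 1 rose and 2 fell with centring (camera adjusted p = 0.726, and adjusted p = 0.799 with an estimated correlation). Of the T and NK cell markers 3 were measured, of the myeloid markers 4 and of the fibroblast and epithelial markers 3, and among these 10 only VIM, a filament protein that these lines also express, passed, with 0.54 ± 0.14 (lost with centring and without each of NCI-H929, MM1S and OPM2, adjusted p up to 0.0978).

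Within single lines the size of the response was counted without a test. At least 2-fold higher were 1299 genes in NCI-H929, 602 in MM1S, 586 in OPM2 and 736 in U266, and at least 2-fold lower were 343, 270, 272 and 159 genes. These counts depended on the scaling. After centring each library on its median the higher genes numbered 674, 345, 358 and 402 and the lower genes 896, 457, 438 and 356, so that the balance turned in NCI-H929, MM1S and OPM2. With the authors' scaling, 126 genes were at least 2-fold higher and 14 at least 2-fold lower in all 4 lines. With a pseudocount of 0.1 the higher genes numbered 2162, 1117, 1067 and 1197. Across genes, which are not independent replicates, the log2 fold changes of 2 lines correlated at r = 0.55 to 0.70. In NCI-H929 the largest changes beside JUN were the increases of NAB2, a corepressor of EGR factors, at 3.37 and of EGR1 at 3.35, and the decreases of PLD6 at -2.25, NOMO1 at -2.17, which has near-identical copies and is uncertain, and the IGF2 receptor IGF2R at -2.13. In MM1S, CYTH4 stood at 2.23 and IGFBP3 at -2.87, where IGFBP3 stood at 1.03 in NCI-H929. In OPM2, the phosphatase DUSP8 stood at 2.93, and the short features AC112777.1 and RMRP at -2.89 and -2.67. In U266, the clock repressor NR1D1 stood at 3.22 and the carboxypeptidase CPVL at -2.76. Across the 4 lines NAB2, EGR1, PLD6, NOMO1, IGF2R and DUSP8 passed the limma threshold, PLD6 not without each of NCI-H929, MM1S and OPM2 (adjusted p up to 0.0836), and CYTH4, IGFBP3, AC112777.1, RMRP, NR1D1 and CPVL did not. PLD6 went the other way in U266, at 0.32. CYTH4 passed with a mean RPKM of at least 5, without OPM2, without U266 and with voom (1.94, adjusted p = 0.00151), and CPVL with a pseudocount of 0.1, with centring, without MM1S, without OPM2 and with voom (-2.43, adjusted p = 0.000513), against 1.06 and -1.06 as reported.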

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

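The values here were compared between the 4 lines of a group, where chance sets apart about 1 group in 20. Of 143 groups of 4 values tested, 10 held a line far from the other 3, and chance would give about 7.2. The U266 DMSO library had 24865004 reads against 46214935 to 48770145 reads in the other DMSO libraries. Without U266 the main comparison called 4648 genes instead of 5081, and without 1 of the other lines it called 3149 to 3552. Each of these fits has fewer residual degrees of freedom, so that the lower count is not specific to the U266 library.

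Single log2 fold changes also stood apart from the other 3 lines. In MM1S these were IER2 at 0.68, CBX5 at -1.15 and CCND1 at -0.29. In NCI-H929 EGR1 stood at 3.35. In OPM2 NFKB2 stood at 2.32 and PMAIP1 at 0.26. In U266 AURKA stood at 0.25, MKI67 at 0.10 and TOP2A at -0.87.

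Of 129 genes followed (those the rule named, list members, and 5 regulators chosen after their values were seen), 2 moved at least 2-fold in opposite directions in different lines. IGFBP3 stood at 1.03 in NCI-H929 and at -2.87 in MM1S, and AC112777.1 at 1.02 in NCI-H929 and at -2.89 in OPM2. Each line had 1 library per group, so that these differences were not tested.

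The number of genes called was set against other groupings of the 8 libraries. Of 35 splits into groups of 4, 32 could be fitted with the cell line as block, and 1 of the 32, the real one, gave 5081 genes, where the highest of the others gave 0. Of the 32, 24 part 2 of the 4 pairs, so that the response of the other 2 lines enters their spread and they do not compare with the real one. Only 8 splits part the pair of every line as the real one does, of which 1, the real one, gave 5081 genes and the highest other gave 0, and 8 splits are too few for a share under 0.05. The others of these 8 swap the groups in some of the lines, so that a response shared by the lines enters their spread too. Their count of 0 would follow from such a response and does not measure chance. For the gene lists, 6 of the 32 splits moved as many lists as the 17 of the real one, and the highest other split moved 19. Among the 8 splits that part every pair, 2 moved as many, the highest other moving 17. Chance was not excluded for the number of lists that camera called with the preset correlation.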

How the results depend on the processing

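Voom on recovered reads, library totals without abundant classes, removal of the GC content and length trend, the lists over genes with GC content only and thinning were chosen after the data were seen. The count of 5081 genes stayed within 1.5 times under both pseudocounts, the RPKM minimum of 5, upper-quartile scaling, quantile normalization, centring, robust empirical Bayes, voom, the reduced library totals and the GC and length correction, with 4285 to 5561 genes. Without a filter, with 34760 genes tested, 1943 genes passed, 1332 higher and 611 lower, of which 1912 were among the 5081. With no replicate block, 0 genes passed (0 higher, 0 lower; limma, 1319 at an unadjusted p under 0.05): the differences between lines then enter the spread. Centring on the median gave 1894 higher and 3550 lower genes, and 3742 of the 5081 calls remained with their sign. Leaving out 1 line gave 3149 to 4648 genes, with 2035 to 2916 higher and 1059 to 1732 lower. These fits have fewer residual degrees of freedom, which alone can end calls. The share of higher genes was 63.6% as reported, 50.3% with upper-quartile scaling, 47.9% with quantile normalization, 34.8% with centring and 57.1% with the reduced library totals. Scaling to equal RPKM sums, which would move values the other way, was not run.

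The 17 lists (7 higher, 10 lower) came to 0 (0 higher, 0 lower) with an estimated correlation and to 14 with no replicate block. Leaving out 1 line gave 16 to 18 lists, and the genes with GC content alone gave 16. Fry did not call several lists that camera called. These were MYC targets (fry adjusted p = 0.0671), initiation factors (0.0525), DNA replication (0.0713), cholesterol genes (0.261), interferon-stimulated genes (0.0671) and proteasome subunits (0.0621). The nonsense-mediated decay list, which camera did not call, passed with fry (adjusted p = 0.0181). The counts of genes at least 2-fold changed rose with a pseudocount of 0.1, since low genes then show larger ratios. They became 2162 higher and 553 lower in NCI-H929, 1117 and 523 in MM1S, 1067 and 503 in OPM2, and 1197 and 271 in U266. With a mean RPKM of at least 5 the lower genes in OPM2 numbered 179, with fewer genes counted. With upper-quartile scaling the lower genes in U266 numbered 244. For these changes beyond what the construction shows, the cause was not tested.

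Of 129 genes followed, 5 changed sign under some alternative, and each of them had not passed the threshold. CCND1 stood at -0.055 with upper-quartile scaling, -0.17 with centring, -0.0095 with the reduced library totals and between -0.019 and 0.13 without 1 line. RPLP1 stood at 0.072 with quantile normalization. Without 1 line, IGFBP3 ranged from -0.96 to 0.34, RMRP from -0.85 to 0.23 and AC112777.1 from -0.90 to 0.41. Calls were gained by RPLP1 (with upper-quartile scaling, centring, a mean RPKM of at least 5, robust empirical Bayes, voom and the reduced library totals), and by CYTH4 and CPVL, whose settings the report gives. Removal of the GC content and length trend ended the calls of DNAJB4 (0.31, adjusted p = 0.145, against 0.48 as reported) and DUSP2 (-0.56, 0.0548, against -0.61). It also ended those of EIF5 and MKI67 (0.27, 0.069, against 0.42). The reduced library totals ended those of BCL2L1 (0.47, adjusted p = 0.0527, against 0.51 as reported) and PSMB9 (0.28, 0.0732, against 0.32). Voom ended those of PSMB9 (0.34, 0.0504) and CIITA (1.01 ± 0.38, 0.0627, against 0.66 ± 0.18), with folds as large or larger and a larger SE. With no replicate block 119 of these genes lost their call, and without a filter 45 did. Leaving out NCI-H929 ended 15 calls, leaving out MM1S 12, leaving out OPM2 15 and leaving out U266 3. PLD6, MCL1, DNAJB4, DUSP2, EIF1, MKI67, PSMB9 and VIM lost theirs without each of NCI-H929, MM1S and OPM2. BCL2L1, CDK4, EIF5, ARRDC4 and CIITA lost theirs without NCI-H929 and without OPM2, CHAC1 and EIF4A1 without NCI-H929 and without MM1S, IRF4 without MM1S and without OPM2, BBC3 without MM1S, IFIT3 without OPM2, and BCL2L1, IRF4 and TOP2A without U266. The 20 genes with the largest shared changes kept their calls except with no replicate block and, for FOSL2, without a filter. The settings foreseen for the comparisons with NAMALWA and over 5 lines, and the count test, were not run. Depth limits the low genes of the U266 DMSO library.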

Other observations

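The tests of this part were chosen after the patterns had been seen, and predictions were written before the tests of technical explanations were run, except for the test of abundant genes taking the counts, whose prediction was written after its value had been seen. The families and regulators in this paragraph were picked for their values, so that their tests across genes, which are not independent, describe them only. Of 438 measured zinc finger genes (symbols in ZNF, ZSCAN, ZKSCAN or ZFP), 281 rose and 3 fell, which is 64.2% higher against 21.6% of the 13648 other genes (odds ratio 6.48, Fisher's exact test p = 2.82e-78; camera p = 0.129 with an estimated correlation). Of 33 ZBTB genes 18 rose and 0 fell (54.5% higher against 22.9% of other genes, Fisher's p = 8.23e-05, camera p = 0.0589 with an estimated correlation). Of 16 lysine demethylases named KDM 9 rose and 0 fell (56.2% against 22.9%, Fisher's p = 0.00404, camera p = 0.0725 with an estimated correlation). These 2 families had medians of 0.49 and 0.51, which stayed above 0 under the 4 other scalings. The acetyltransferases EP300 and CREBBP rose by 1.88 ± 0.10 and 1.35 ± 0.11 (SE, 4 lines), the transcription kinase CDK12 by 1.32 ± 0.10, the remodeller CHD2 by 1.47 ± 0.12 and the bromodomain protein BRD2 by 1.44 ± 0.15, each at least 2-fold in all 4 lines. Of 117 small nucleolar RNAs 57 fell and 0 rose (48.7% lower against 12.8% of other genes, Fisher's p = 9.26e-21, camera p = 0.0918 with an estimated correlation), with a median of -0.65 that lay between -0.84 and -0.68 under the other scalings; these short transcripts are poorly caught by libraries of long RNA.

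Basal transcripts set the lines apart in DMSO, given as values of 1 library each. FGFR3 stood at 459 RPKM in OPM2 and at 3.48 in NCI-H929, 0.31 in MM1S and 0.106 in U266. CCND1 stood at 569 RPKM in U266, 68.8 in NCI-H929, 20.6 in MM1S and 0.059 in OPM2. MAF stood at 144 RPKM in MM1S and 0.738 in U266, and MYC at 265 in MM1S and 2.40 in U266. S100A9, a myeloid marker, stood at 214 RPKM in NCI-H929 and at most at 0.569 in the other lines. Of the other myeloid genes, S100A8 stood at 34.7 RPKM in NCI-H929 (at most 0.041 in the other lines), CD68 at 37.4 (at most 8.36) and CSF1R at 3.98 (at most 0.111), while LYZ and CD14 stood at 0.025 and 0.023 in NCI-H929. Of 13 myeloid markers, 3 had an RPKM of 10 or more in this line and 0 in each of the others.

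The rise of the zinc finger genes was set against technical explanations. Their median log2 fold change was 0.593 over the 431 members with GC content, where 95% of the medians of 10000 random lists of other genes matched on GC content, length and expression lay between 0.124 and 0.212. The median without U266, whose libraries differ most in depth, was 0.617. Both values argue against GC content, length and depth as the whole cause, and the median was 0.39 to 0.56 under the 4 other scalings. Camera's p for this family was 0.129 with an estimated correlation of 0.242 between its genes, and reads shared between paralogs were not tested. A response of these transcripts to CMLD010509 may account for the rise, as a hypothesis from the same data.

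A few abundant genes taking most of the counts would lower all other genes alike, but beside the fall of ribosomal protein genes the median of all other genes was 0.087 (0.041 to 0.129 in the single lines), and the share of reads on the 10 genes with most reads was lower with CMLD010509 in every line (3.6 to 6.05%, against 5.01 to 8.25% in DMSO). Against 10000 lists of other genes matched on GC content, length and expression, the median of -0.52 lay below the central 95%, -0.444 to -0.278, and with the GC content and length trend removed it was -0.47, which argues against GC content and length as the whole cause. The matched lists themselves had a median of -0.383, though they were less abundant (7.455 against 8.002 on the log2 scale), so that the excess over them may come from abundance. A shift of abundant against rare transcripts with CMLD010509 stays open, since quantile normalization brought the median to -0.22 and RPKM carries no absolute RNA amount.

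The number of genes at least 2-fold higher was 1.76 times as large in NCI-H929 as in the next line, U266. After thinning every library to the reads of the shallowest the ratio was 1.79. The NCI-H929 libraries had close totals, 46214935 and 46774444 reads, so that thinning says little about a depth difference within this line. After centring each library on its median the ratio was 1.68, with 674 and 402 genes, which argues against scaling as the whole cause. A stronger response of this line may be one explanation and a difference between single libraries another. With 1 library per group in each line these were not separated.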
